A study of Mus musculus with 9 samples.

How the data were processed

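Total RNA of a mouse cell line was measured on 9 Affymetrix Mouse 430 2.0 arrays, 3 for each of 3 groups. The line is BC3H1, a brain tumour line with myogenic (muscle-like) properties. Rapamycin is an inhibitor of the mTOR complex 1 kinase, which it binds together with the protein FKBP12. The groups were rapamycin-sensitive cells given the solvent DMSO for 24 h, sensitive cells given 100 nM rapamycin for 24 h, and a resistant line. Per the labels' protocols, the resistant line was obtained by 6 months of culture in 1 uM rapamycin and stayed in 1 uM rapamycin. Dose and exposure time therefore differ between the 2 rapamycin groups, and a resistant group without rapamycin was not analysed here. The resistant and DMSO cells differ in line, in the months of culture in rapamycin and in the presence of the drug, which cannot be told apart. There was 1 resistant line, so its p-values do not separate resistance from other traits of that line. Groups and replicate numbers came from the sample titles. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

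The deposited values are linear intensities (signals), 1 per probe set and array, made by the authors with GCOS 1.4, per the submitters' processing notes. GCOS is the Affymetrix array software; the summary algorithm and its settings are not given in the sources used here. Each array's trimmed mean, leaving out 2% of the values at either end, was 250, which was taken from the values. Detection calls, hybridization dates and scan batches were not used here, so no batch could be tested. The number of arrays limits the precision of every value.

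Of 45101 probe sets, 64 were controls, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none. Only probe sets with 1 symbol were used for genes, 18193 in all. Gene IDs of 34741 probe sets were found in a table of mouse genes (assembly GRCm38.p6), and no symbol needed an update. That table served only for names and for the order of genes along chromosomes; the files name no genome build, so no coordinates are given.

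Values were analysed as log2(signal + 16). They were kept as deposited because the arrays' 75th percentiles differed by 0.17 on that scale, under a limit of 0.2 set in advance. Changes on this scale understate the change of dim genes. Probe sets with a mean above the 40th percentile (a signal of about 22.2) were kept, and each gene was represented by its probe set with the highest mean, which left 12715 genes. A linear model over all 9 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 3 comparisons. An adjusted p of a gene is from this limma fit unless an alternative is named; values of single probe sets are from a fit of all probe sets above the filter. The ± after a log2 change is its standard error, with n = 3 arrays per group. Signals are given as mean ± SD of 3 arrays.

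Gene lists (32, plus 6 lists of cell type or identity markers) held 1100 distinct genes, of which 1017 had a usable probe set and 911 were tested. The lists were tested with camera at a preset correlation of 0.01 between genes, for lists with at least 5 tested members, adjusted over 36 lists and 3 comparisons. The same test with a correlation estimated from the data, and fry, were alternatives. Named genes followed a rule: per comparison, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group mean reached the median of tested genes, leaving out clone, EST and predicted-gene names. Up to 4 called members of each list with the largest change were added, with 15 genes of the mTOR pathway, cell growth and drug transport whatever their result. Of those 15, Rps6kb1 and Irs2 were not analysed here, and another is not reported here. Design, lists, rule and alternatives were fixed before the data were examined, except where the text says otherwise.

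The fit was tested on simulated arrays with the means and variances of the 12715 genes, 200 of them changed, 50 for each size. For the sensitive cells with and without rapamycin, 40% of genes changed by 0.5 on the log2 scale were called, 70% of those changed by 1, 94% of those changed by 2 and 96% of those changed by 3. For the resistant against the sensitive DMSO cells the shares were 44%, 76%, 92% and 100%. For the resistant against the sensitive rapamycin cells they were 58%, 64%, 88% and 100%. These shares hold for arrays with few changed genes. The adjusted p depends on the share of changed genes, and 35.6% to 56.5% of genes were called in the data. The shares are therefore not the sensitivity of the fit in the data. Among the 12515 unchanged genes, 12, 8 and 9 were called in these 3 simulations, which was 7.41%, 4.88% and 5.49% of all calls there. The simulated noise was normal and independent between genes and arrays, and no simulated array stood apart.

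Alternatives were other pseudocounts (1 and 64), quantile normalization, centring on the 75th percentile, other filters and other rules for probe sets. Others were eBayes without a trend or robust, a fit of only the groups compared, the replicate number as a block, and leaving out each array in turn. RNA quality was compared through the 3-prime and 5-prime control probe sets of Gapdh and Actb and the spiked-in bacterial transcripts, with exact two-sided permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1. Plots were drawn with matplotlib 3.10.9.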

Results

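Gene expression was compared between rapamycin-sensitive BC3H1 cells in DMSO, the same cells after 24 h in 100 nM rapamycin, and a resistant line kept in 1 uM rapamycin, with 3 arrays per group. The comparisons ask which transcripts respond to the drug in sensitive cells and which differ in the resistant line. After the authors' scaling, the median signal lay between 33.4 and 44.2 on 8 arrays. The third DMSO array stood apart with a median of 66.0, and 17.4% of its probe sets had a signal below 16, against 29.4% to 34.8% on the other arrays. Correlations over genes were 0.955 to 0.980 within the DMSO group, 0.976 to 0.980 within the sensitive rapamycin group and 0.987 within the resistant group. Between groups they ran from 0.865 to 0.953.

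**Figure D1:**
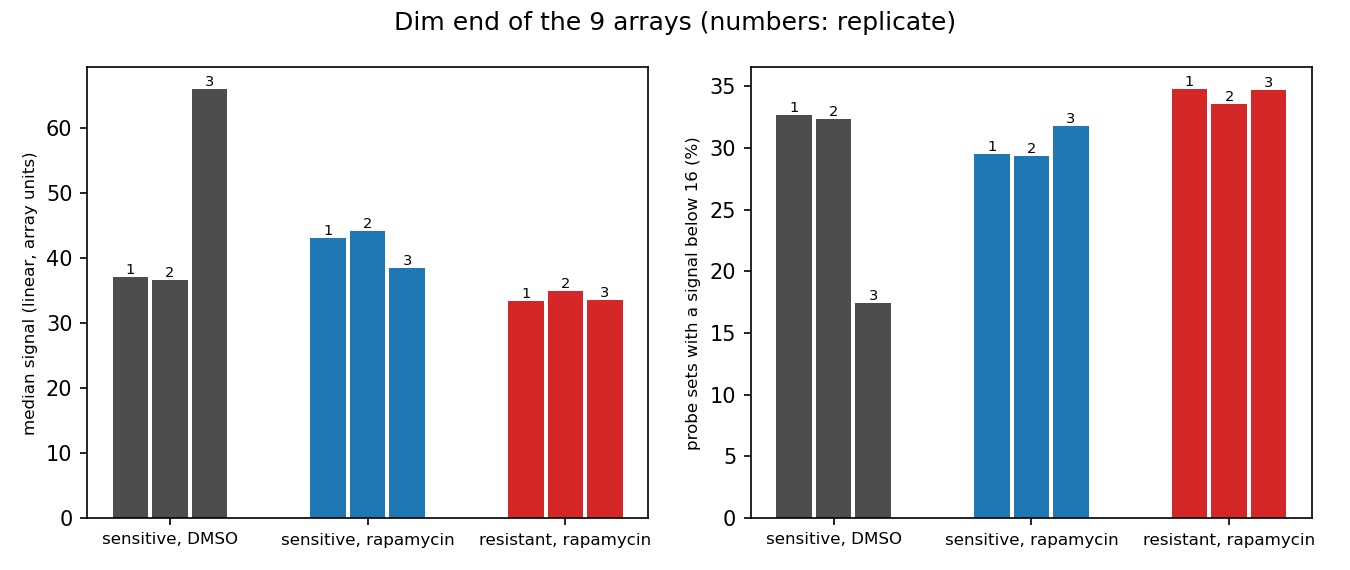
Median signal (left, linear array units) and percentage of probe sets with a signal below 16 (right) on each array; each bar is 1 array, labelled with its replicate number. The third DMSO array has a median of 66.0 and 17.4% of probe sets below 16.

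RNA quality was read from control probe sets. The log2 difference between the 3-prime and 5-prime probe sets of Actb was 0.17 ± 0.008 (SD, n = 3) in the DMSO cells, 0.19 ± 0.04 in the sensitive rapamycin cells and 0.33 ± 0.02 in the resistant cells. The resistant arrays lay above all others (exact permutation p = 0.1 against either group, the smallest possible). For Gapdh the largest difference between group means was 0.07, the sensitive rapamycin arrays lying below all others (exact permutation p = 0.1 against either group), and the spiked-in transcripts averaged 11.2 to 11.3 in log2 signal in the 3 groups, with overlapping values.

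In sensitive cells, 24 h of rapamycin lowered genes of cell division, ribosome production and amino acid synthesis. Lists of lysosome and extracellular matrix genes rose in camera (adjusted p = 0.142 and 0.407 with an estimated correlation). All 33 tested members of the mitosis list fell, with a median log2 change of -2.17, and 37 of 38 DNA replication genes fell, with a median of -1.95. Mcm5, a subunit of the replicative helicase, dropped from a signal of 3710 ± 186 to 396 ± 17.1 (log2 change -3.17 ± 0.08, adjusted p = 6.52e-14). Cdc6, which loads the helicase at origins, changed by -3.15 ± 0.19. Of the mitotic kinases, Aurka changed by -2.76 ± 0.07 and Ttk by -2.47 ± 0.11. Of 12715 genes tested, 4523 (35.6%) were called, 2592 higher and 1931 lower, against 2184 and 2031 with arrays centred on the 75th percentile. On the log2(signal + 16) scale 265 rose and 503 fell at least 2-fold.

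Other genes of replication and mitosis also fell. Lrr1 (-3.47 ± 0.31), the kinetochore gene Ska1 (-3.14 ± 0.14), the cohesion factor Dscc1 (-3.13 ± 0.15) and the exonuclease Exo1 (-2.98 ± 0.22) were among the 10 largest, with Gins1 (-2.92 ± 0.13), Mcm3 (-2.82 ± 0.08) and Rad51ap1 (-2.79 ± 0.16). Among the G1 phase genes, 10 of 24 fell and 5 rose. The E-type cyclins Ccne1 (-1.92 ± 0.09) and Ccne2 (-2.43 ± 0.14) fell, as did Skp2, the receptor of the ubiquitin ligase that targets p27 (-1.44 ± 0.08). Cdkn1b, which encodes p27, rose by 0.50 ± 0.10 (adjusted p = 0.000611, and 0.063 with the mean of its probe sets), and Ccnd1 rose by 0.37 ± 0.08.

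Of 42 ribosome biogenesis genes, 33 fell and 1 rose, with Dkc1, Lyar, Nop58 and Nhp2 changed by -1.25, -1.25, -1.19 and -1.16. In the list of amino acid synthesis and transport, which gathers targets of the transcription factor ATF4, 23 of 29 fell. Psph, the last enzyme of serine synthesis, changed by -2.42 ± 0.08, from 2832 ± 253 to 515 ± 41.8. Psat1 (-1.96 ± 0.10), the mitochondrial folate enzyme Mthfd2 (-2.31 ± 0.14) and Cth (-2.26 ± 0.09) moved with it. Of 19 cytosolic aminoacyl-tRNA synthetases 18 fell and 1 rose, led by Cars (-1.14 ± 0.09) and Tars (-0.98 ± 0.08). These 5 lists were shifted in camera (adjusted p between 2.35e-42 and 7.04e-11), and also with an estimated correlation (adjusted p = 0.0267 for mitosis, DNA replication, ribosome biogenesis and ATF4 targets and 0.0424 for the synthetases). The counts of falls adjusted over the list alone were 33, 37, 33, 23 and 18 for mitosis, DNA replication, ribosome biogenesis, the ATF4 targets and the synthetases.

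Further lists fell in camera but not with an estimated correlation. Glycolysis fell in 14 of 21 members and rose in 3 (adjusted p = 0.0506 with an estimated correlation); the lactate carriers Slc16a3 (-1.49 ± 0.13) and Slc16a1 (-1.03 ± 0.08) fell, and Eno2 rose (1.18 ± 0.25). Heat shock proteins and proteasome subunits fell in 22 of 34 members and rose in 1 (adjusted p = 0.405 with an estimated correlation), among them Hsph1 (-0.87 ± 0.07). Their camera adjusted p was 0.000201 and 1.46e-08. The G1 phase list was also shifted down (adjusted p = 0.0146, and adjusted p = 0.407 with an estimated correlation). Falls numbered 14, 26 and 10 in these 3 lists when adjusted over the list alone.

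Among genes admitted by the naming rule, the largest rises were in the nuclear noncoding RNAs Neat1 (3.38 ± 0.23, from 237 ± 104 to 2465 ± 458) and Malat1 (2.89 ± 0.34). Their probe sets disagreed: the other Neat1 probe set changed by -0.04 (adjusted p = 0.967), and 1 of 7 Malat1 probe sets was called lower, at -1.21. Gas6, a ligand of the TAM receptor kinases, rose by 1.92 ± 0.13, Crebrf by 1.88 ± 0.14, the muscle ubiquitin ligase Fbxo32 by 1.77 ± 0.17 and Thbs1 (thrombospondin 1) by 1.68 ± 0.10. Of 42 lysosome and autophagy genes, 27 rose and 2 fell; Ctsa (1.10 ± 0.08), Neu1 (0.94 ± 0.14), Naglu (0.93 ± 0.15) and Glb1 (0.90 ± 0.09) are hydrolases of the lysosome; with the mean of its probe sets Ctsa changed by 0.36 (adjusted p = 0.0566). Of 37 genes for collagens and extracellular matrix 24 rose and 3 fell, among them fibronectin, Fn1 (1.01 ± 0.10), and of 22 smooth muscle contractile genes 11 rose, with vinculin, Vcl, at 0.88 ± 0.09. The interferon response list rose in 22 of 36 members and fell in 2, with Gbp2 at 1.56 ± 0.21 and Ifit3 at 1.25 ± 0.14; without the first sensitive rapamycin array 13 rose. These lists were called in camera (adjusted p between 4.13e-07 and 0.00303), but with an estimated correlation the adjusted p = 0.142 for lysosome and autophagy, 0.407 for matrix and for smooth muscle, and 0.238 for interferon. Rises adjusted over the list alone numbered 27, 27, 12 and 23 in these 4 lists.

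The list of insulin, IGF and growth factor receptors and ligands rose in 14 of 37 members and fell in 2, including Igf1r (1.17 ± 0.11) and Igf2r (1.05 ± 0.16), and TGF-beta and BMP signalling rose in 14 of 32 and fell in 2, including Tgfb3 (1.43 ± 0.12) and Ltbp3 (0.95 ± 0.08). Their camera adjusted p was 0.0106 and 0.0174, and adjusted p = 0.242 and 0.407 with an estimated correlation. With the mean of a gene's probe sets the adjusted p was 0.0593 and 0.0999, which ended both calls. Counts adjusted over the list alone were also 14 and 2 in either list. The immediate early list as a whole was not shifted (adjusted p = 0.284): of 31 members 6 rose and 7 fell (6 and 9 adjusted over the list alone). Of those that fell, Ier2 (-2.13 ± 0.12), Fos (-2.13 ± 0.19), Fosl1 (-2.04 ± 0.16) and Egr1 (-1.93 ± 0.16) changed most. Of the pathway of the drug itself, Irs1 rose (0.98 ± 0.13), Eif4ebp1 (-0.71 ± 0.09) and Eif4e (-0.55 ± 0.08) fell, and Mtor (0.27 ± 0.13, adjusted p = 0.125), Akt1 (-0.16 ± 0.09, adjusted p = 0.217) and Fkbp1a, which encodes FKBP12 (-0.08 ± 0.08, adjusted p = 0.461), did not pass the test. Without the third DMSO array Mtor and Akt1 passed (adjusted p = 0.0306 and 0.0462), as did Fkbp1a under quantile normalization (adjusted p = 0.0488). Myc rose by 0.57 ± 0.13 (adjusted p = 0.00258), and Hif1a changed by 0.06 ± 0.08 (adjusted p = 0.601). The P-glycoprotein gene Abcb1b fell (-1.17 ± 0.14), though not with the mean of its probe sets (-0.53, adjusted p = 0.109). Abcb1a changed by -0.77 ± 0.33 (adjusted p = 0.0839) and passed with a pseudocount of 64 (adjusted p = 0.0368), without a trend in eBayes (adjusted p = 0.0285) and with the mean of its probe sets (adjusted p = 0.0384). Camera called 15 of 36 lists, 7 up and 8 down, and 5 with an estimated correlation.

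The resistant line, compared with sensitive DMSO cells, showed low interferon response genes and high Myc and ribosome biogenesis genes. Of 36 interferon response genes 34 fell, with a median log2 change of -3.28; Usp18, an inhibitor of interferon signalling that interferon itself induces, dropped from 2344 ± 351 to 11.5 ± 7.50 (-6.45 ± 0.15, adjusted p = 2.88e-15). The resistant Usp18 signal was below the filter limit, where the pseudocount limits the change. Xaf1 (-6.50 ± 0.24), Trim30a (-6.39 ± 0.13) and Oas1a (-6.02 ± 0.27) also fell. Myc rose from 293 ± 74.8 to 4227 ± 102 (3.81 ± 0.13, adjusted p = 2.29e-13). Of 42 ribosome biogenesis genes, 39 rose (median 0.98), led by Noc2l (2.34 ± 0.11), Gnl3, which encodes nucleostemin (1.96 ± 0.07), and Ppan (1.90 ± 0.13). In all 6581 genes (51.8%) were called, 3299 higher and 3282 lower, against 3776 and 2754 with arrays centred on the 75th percentile, which moved the median change of all genes from -0.07 to 0.03; 693 rose and 1270 fell at least 2-fold.

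Actg2, smooth muscle gamma actin, fell from 3479 ± 440 to 21.6 ± 5.91 (-6.54 ± 0.11), a signal below the filter limit, where the pseudocount limits the change. The smooth muscle list fell in 17 of 22 members, among them calponin, Cnn1 (-4.71 ± 0.13), and transgelin, Tagln (-2.55 ± 0.10). Of the skeletal muscle genes 10 of 27 fell and 8 rose, also when adjusted over the list alone, and the list was not shifted (adjusted p = 0.538); the acetylcholine receptor subunit Chrna1 fell (-4.22 ± 0.23), and the troponins Tnnt1 (3.49 ± 0.40) and Tnnc2 (3.19 ± 0.36) rose. Collagen and matrix genes fell in 31 of 37 and rose in 2, including Tnc (-3.73 ± 0.15), Ccn2 (-3.75 ± 0.11) and the protease inhibitor Timp1 (-3.63 ± 0.09). Matrix proteases fell in 16 of 22 and rose in 1, including Plat (-3.04 ± 0.09). Camera called these 3 falling lists (adjusted p = 4.13e-08, 1.65e-11 and 3.25e-06); with an estimated correlation the adjusted p = 0.148 for smooth muscle, 0.201 for matrix and 0.0784 for the proteases. Falls numbered 17, 31 and 18 adjusted over the list alone.

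Inflammatory cytokines and chemokines fell in 14 of 20 members and rose in 1, among them Ccl5 (-2.97 ± 0.25), Ptgs2 (-2.57 ± 0.13) and Vcam1 (-2.41 ± 0.10). This list, interferon response and ribosome biogenesis were called in camera (adjusted p = 5.2e-06, 1.65e-22 and 1.07e-18) and each had an adjusted p = 0.0267 with an estimated correlation. Adjusted over the list alone, 15 inflammatory and 34 interferon genes fell and 39 ribosome biogenesis genes rose. Immediate early genes fell in 22 of 31 and rose in 1 (adjusted p = 0.0605 with an estimated correlation), including Egr1 (-3.78 ± 0.16) and the phosphatase gene Dusp1 (-2.67 ± 0.11). Receptors and ligands of growth factors fell in 20 of 37 and rose in 5 (adjusted p = 0.165 with an estimated correlation). Grb10, an adaptor that binds the insulin receptor, went from 911 ± 1.46 to 21.3 ± 9.51 (-4.67 ± 0.15), also below the filter limit. The unfolded protein response list fell in 14 of 24 and rose in 1 (adjusted p = 0.407 with an estimated correlation), including Xbp1 (-2.34 ± 0.08). Camera called these last 3 lists with an adjusted p of 9.36e-07, 0.00146 and 0.00452, and 22, 20 and 14 members fell, adjusted over the list alone.

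Besides ribosome biogenesis, 5 lists were shifted up. Cholesterol synthesis and uptake rose in 14 of 20 members and fell in 2 (adjusted p = 0.0506 with an estimated correlation), with Sqle at 1.63 ± 0.08 and Hmgcs1 at 1.30 ± 0.08, and Ebp fell (-1.61 ± 0.09). Fatty acid synthesis rose in 9 of 17 and fell in 2 (adjusted p = 0.407 with an estimated correlation), with Fasn at 1.10 ± 0.10. Cytosolic ribosomal proteins rose in 18 of 32 (adjusted p = 0.482 with an estimated correlation), and under quantile normalization 18 rose and 3 fell. Translation factors rose in 17 of 30 and fell in 2 (adjusted p = 0.471 with an estimated correlation), and oxidative phosphorylation rose in 27 of 44 and fell in 1 (adjusted p = 0.497 with an estimated correlation); under quantile normalization 7 oxidative phosphorylation genes fell. Camera called these 5 lists with an adjusted p between 1.72e-05 and 0.0242, and 14, 10, 19, 20 and 27 members rose, adjusted over the list alone. The Actb 3-prime to 5-prime difference was also higher on the resistant arrays, 0.33 against 0.17. Camera called 14 of 36 lists, 6 up and 8 down, and 3 with an estimated correlation.

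Other large rises were in Prph, an intermediate filament of peripheral neurons (4.15 ± 0.32, from 7.52 ± 6.66 to 395 ± 66.6), and Rragd, a Rag GTPase that recruits mTOR complex 1 to lysosomes (3.74 ± 0.33, from 18.8 ± 15.2 to 421 ± 8.82). The DMSO signals of Prph and Rragd were below the filter limit, where the pseudocount limits the change. Skp2 rose by 1.82 ± 0.08 and Rictor, a subunit of mTOR complex 2, by 1.59 ± 0.12. Cell division lists were not shifted against DMSO cells: 12 of 33 mitosis genes rose and 4 fell (adjusted p = 0.0917), and 11 of 38 replication genes rose and 11 fell (adjusted p = 0.372). Ccnd1 was lower (-1.32 ± 0.08), Mtor (0.60 ± 0.13) and Akt1 (0.30 ± 0.09) were higher, and Eif4ebp1 was higher by 0.29 ± 0.09. The call of Eif4ebp1 was lost without the second resistant array (adjusted p = 0.0616), without a trend in eBayes (0.0575), under quantile normalization (0.0699) and with the mean of its probe sets (0.275), and that of Akt1 with the mean of its probe sets (0.124). Irs1 was lower (-0.75 ± 0.13), and Eif4e (0.12 ± 0.08, adjusted p = 0.245) did not pass. Cdkn1b changed by 0.28 ± 0.10 (adjusted p = 0.0237); its call was lost without the third DMSO array (adjusted p = 0.0897), the first (0.0626) or the third (0.0794) resistant array, without a trend in eBayes (0.0809) and with the mean of its probe sets (0.861). The Fkbp1a probe set used gave 0.27 ± 0.08, and 3 of its 5 were called higher, while another gave -0.05 (adjusted p = 0.721), and under quantile normalization the call of Fkbp1a was lost (adjusted p = 0.0718). Both P-glycoprotein genes were lower, with changes of -2.29 ± 0.33 for Abcb1a and -0.68 ± 0.14 for Abcb1b; with the mean of its probe sets Abcb1b did not pass (-0.15, adjusted p = 0.626). The brightest Hif1a probe set changed by 0.02 ± 0.08 (adjusted p = 0.824), and another was called lower at -0.47; with the mean of its probe sets Hif1a was lower (-0.26, adjusted p = 0.033).

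Between the 2 rapamycin groups, which differ in dose and exposure time as well as in line, the resistant cells had higher DNA replication and ribosome biogenesis genes and lower interferon response and inflammatory genes. Of the tested members, 33 of 33 mitosis, 38 of 38 DNA replication and 42 of 42 ribosome biogenesis genes rose, with median log2 changes of 2.32, 2.06 and 1.72 (for mitosis adjusted p = 0.0506 with an estimated correlation). Mcm3 rose from 281 ± 14.7 to 3115 ± 43.1 (3.40 ± 0.08, adjusted p = 7.65e-16), Cenpa, the centromeric histone, by 3.44 ± 0.09, and Lyar by 3.08 ± 0.09. The transferrin receptor, Tfrc, rose to a signal of 2410 ± 164 (4.32 ± 0.12). In all 7186 genes (56.5%) were called, 3353 higher and 3833 lower, against 3892 and 3240 with arrays centred on the 75th percentile and 3603 and 3595 under quantile normalization, so the balance of directions turned with the scaling; 1313 rose and 1741 fell at least 2-fold. The Actb 3-prime to 5-prime difference was 0.33 on the resistant and 0.19 on the sensitive rapamycin arrays.

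Interferon response genes fell in 33 of 36 (median -3.44), with Xaf1 at -7.16 ± 0.24 and Ifit3 at -6.09 ± 0.14, and inflammatory genes fell in 14 of 20 and rose in 1. Camera called these 5 lists (adjusted p between 1.65e-22 and 0.000126). With an estimated correlation, DNA replication and interferon (adjusted p = 0.0286), ribosome biogenesis (0.0267) and inflammatory genes (0.0393) passed, and mitosis did not (adjusted p = 0.0506). Adjusted over the list alone, 33, 38 and 42 members of the 3 rising lists rose, and 34 interferon and 14 inflammatory genes fell. ATF4 targets rose in 19 of 29 and fell in 5 (adjusted p = 0.0784 with an estimated correlation), led by Mthfd2 (3.10 ± 0.14) and Psph (2.67 ± 0.08). The synthetases rose in 16 of 19 (adjusted p = 0.0784 with an estimated correlation), with Tars at 2.86 ± 0.08. Glycolysis rose in 12 of 21 and fell in 3 (adjusted p = 0.0815 with an estimated correlation), and heat shock and proteasome genes rose in 25 of 34 and fell in 3 (adjusted p = 0.471 with an estimated correlation). Camera called these 4 lists (adjusted p between 3.21e-07 and 0.00222), and 20, 16, 12 and 26 members rose, adjusted over the list alone.

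Matrix genes fell in 32 of 37, smooth muscle genes in 20 of 22 and lysosome and autophagy genes in 27 of 42 with 4 higher; with an estimated correlation their adjusted p was 0.179, 0.142 and 0.201. Thbs1 (-4.41 ± 0.10), Cnn1 (-4.70 ± 0.13) and the cathepsin Ctsb (-1.92 ± 0.09) were examples. Matrix proteases fell in 20 of 22 with 2 higher, growth factor receptors and ligands in 23 of 37 with 1 higher, immediate early genes in 19 of 31 with 4 higher and TGF-beta and BMP genes in 19 of 32 with 5 higher. With an estimated correlation their adjusted p was 0.0815, 0.114, 0.165 and 0.348. Camera called these 7 lists (adjusted p between 1e-12 and 0.00486), and 32, 20, 29, 20, 24, 20 and 19 members fell, adjusted over the list alone. Cholesterol synthesis (13 of 20 higher, 3 lower), translation factors (18 of 30 higher, 2 lower), oxidative phosphorylation (27 of 44 higher, 4 lower) and ribosomal proteins (12 of 32 higher) were shifted up in camera (adjusted p between 0.000425 and 0.0146). With an estimated correlation their adjusted p was 0.114, 0.471, 0.566 and 0.657. The count of ribosomal proteins was 7 without the first sensitive rapamycin array or the third resistant array and 19 without the third DMSO array. The rises adjusted over the list alone were 13, 18, 27 and 8. Camera called 20 of 36 lists, 11 up and 9 down, and 4 with an estimated correlation. Centring arrays on the 75th percentile moved the median change of all genes from -0.08 to 0.05, so changes of that size in this comparison have no settled direction. Of the fixed genes, Ccnd1 (-1.69 ± 0.08) and Irs1 (-1.74 ± 0.13) were lower, Eif4ebp1 (1.00 ± 0.09) and Eif4e (0.67 ± 0.08) higher, and Cdkn1b changed by -0.22 ± 0.10 (adjusted p = 0.0664). Cdkn1b passed without the third DMSO array (adjusted p = 0.0434), without the third sensitive rapamycin array (0.0071) and under quantile normalization (0.043). Myc (3.25 ± 0.13) and Akt1 (0.46 ± 0.09) were higher and Abcb1a (-1.52 ± 0.33) was lower; with the mean of its probe sets Akt1 lost its call (adjusted p = 0.528). Abcb1b was higher by 0.49 ± 0.14, though not with the mean of its probe sets (adjusted p = 0.208), and Hif1a changed by -0.04 ± 0.08 (adjusted p = 0.733). Mtor changed by 0.34 ± 0.13 (adjusted p = 0.0331), and its call was lost without the second (adjusted p = 0.0848) or the third (0.141) sensitive rapamycin array, the first (0.119) or the third (0.0625) resistant array, and without a trend in eBayes (0.0896). Fkbp1a changed by 0.35 ± 0.08, but by -0.26 (adjusted p = 0.0255) without probe sets with an _x_ or _s_ suffix; of its 5 probe sets 3 were called higher (0.31 to 0.40), 1 lower (-0.26) and a dim one not (-1.02, adjusted p = 0.152).

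**Figure D2:**
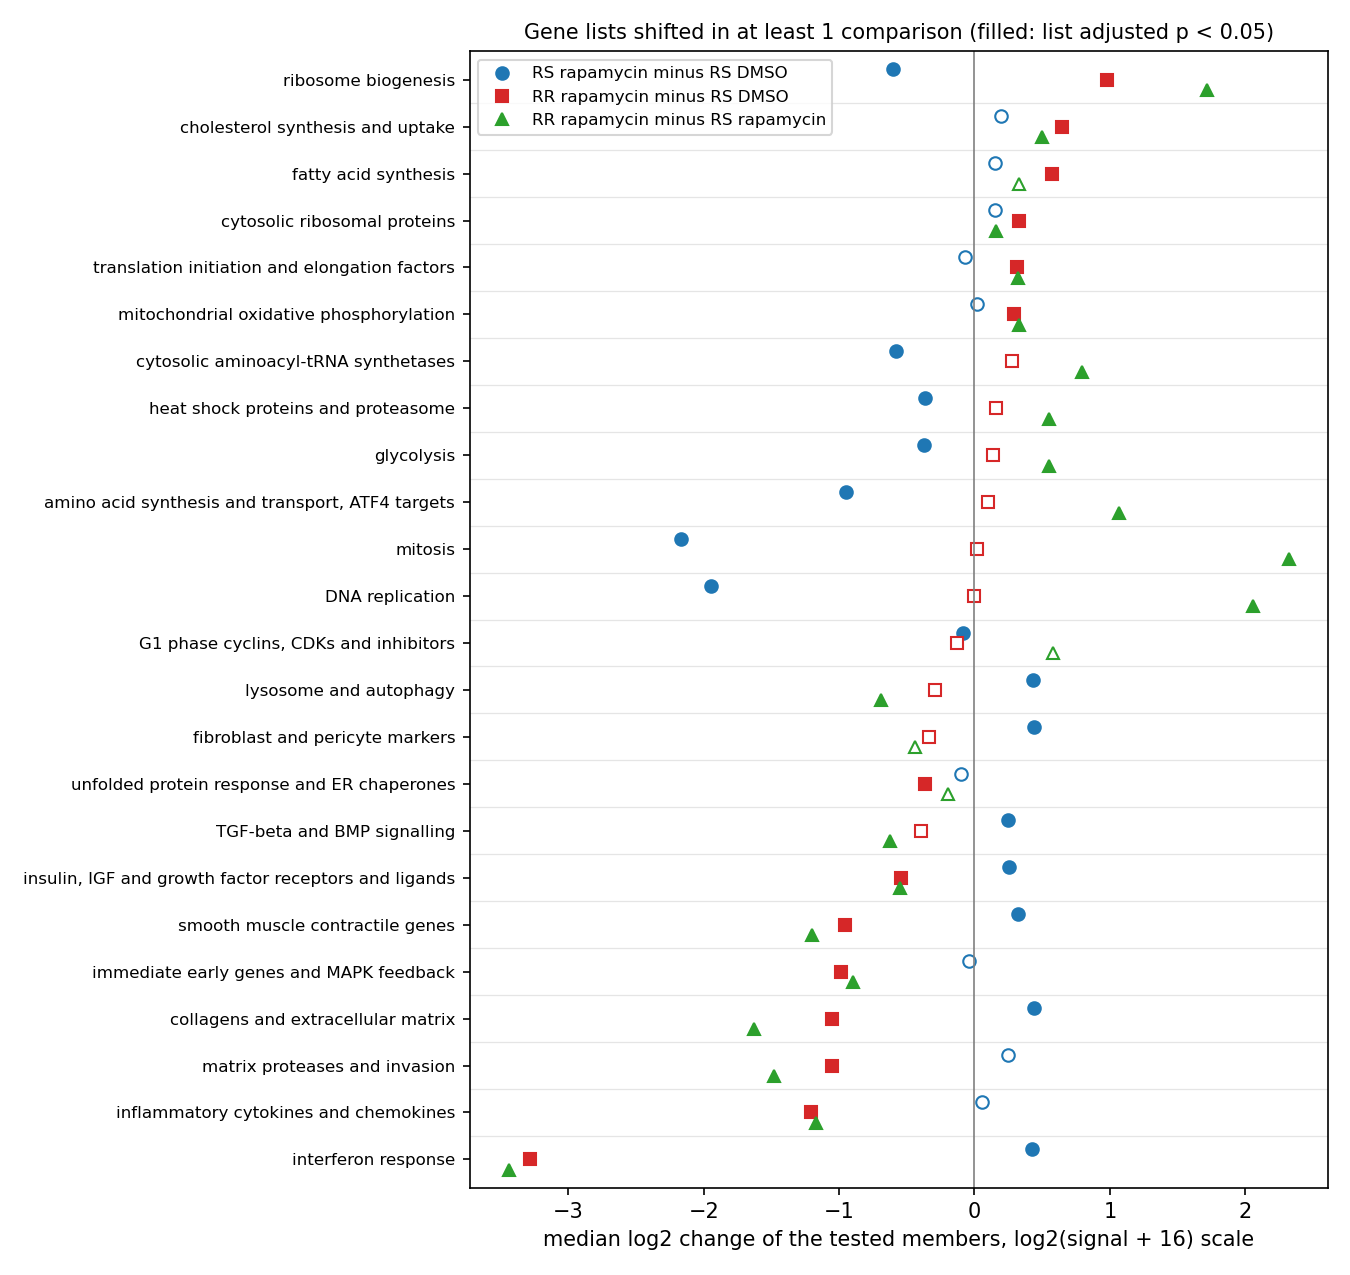
Median log2 change of the tested members, on the log2(signal + 16) scale, for each gene list that camera called in at least 1 of the 3 comparisons; filled symbols are lists called in that comparison. Mitosis lies at -2.17 for rapamycin in sensitive cells and at 2.32 between the rapamycin groups, and interferon response at -3.28 for the resistant line against DMSO cells.

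**Figure D3:**
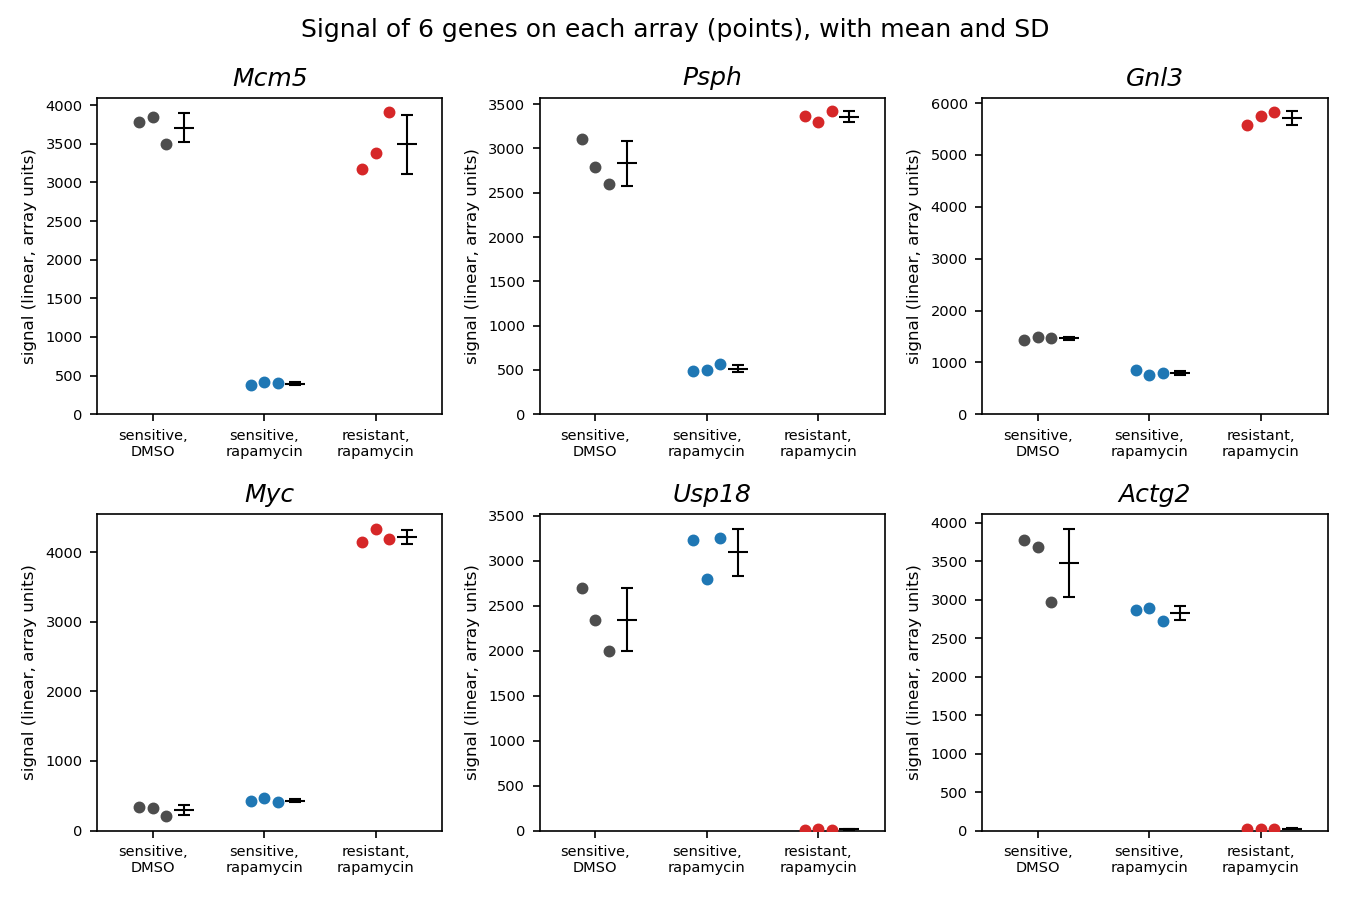
Signal (linear array units, axes starting at 0) of 6 genes on each array, with the mean and SD of 3 arrays beside the points. Mcm5 and Psph are lowest in the sensitive rapamycin cells, Myc and Gnl3 are highest and Usp18 and Actg2 lowest in the resistant cells.

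The comparisons share arrays, so their overlaps were set against 2 references: the count for independent lists, and 100 simulations of unchanged groups with the shared arrays. Of the genes that rose with rapamycin in sensitive cells, 67.1% (1739 of 2592) were lower in the resistant cells than in the sensitive rapamycin cells; of those that fell, 76.9% (1485 of 1931) were higher there. Independent lists would share 781 and 509 genes, and simulated unchanged groups shared at most 1. In unchanged groups almost no gene passes the adjusted p, so that low count was set in advance. It does not measure what shared arrays add among changed genes. The change between the rapamycin groups is also the difference of the 2 changes against DMSO cells. A change absent from the resistant line must appear there with the opposite sign, so independent lists are no neutral reference. The covariance of the changes was -0.32, against -0.03 simulated, and the correlation -0.56, against -0.50 for unchanged groups sharing arrays. Both comparisons use the sensitive rapamycin arrays. The simulated covariance already holds the spread between arrays of a group, so that spread does not account for the excess in covariance. An effect common to all sensitive rapamycin arrays was not simulated and may be part of it.

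Genes changed the same way in both comparisons against DMSO cells numbered 1260, with 812 higher and 448 lower, against 672 and 498 for independent lists and 0 in the simulations. That 0 was again set in advance, since almost no gene is called in unchanged groups. Changes in opposite directions against DMSO cells were more common. Of the genes that rose with rapamycin in sensitive cells, 1003 were lower in the resistant line than in DMSO cells, and 777 were not called there. Of those that fell, 849 were higher there and 634 were not called. No reference count was computed for these opposite changes. The correlation of the changes over genes was 0.005, against 0.50 for unchanged groups sharing the DMSO arrays, and the covariance was 0.002 against 0.03; genes are not independent replicates. Genes changed the same way in the resistant cells against both sensitive groups numbered 5189, 2473 higher and 2716 lower, against 870 and 989 for independent lists and at most 1 in the simulations. These changes differ only by the change with rapamycin in sensitive cells, so independent lists are no neutral reference here either. Their covariance was 0.70, against 0.03 simulated, and their correlation 0.83, against 0.50. The spread between arrays of a group is again in the simulated covariance and does not account for the excess in covariance. An effect common to all resistant arrays was not simulated and may be part of it. Part of the excess of the 812 genes higher in both comparisons against DMSO cells may come from the shared arrays, which are too few to split. The 448 lower genes were fewer than independent lists would share.

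Marker lists of other cell types were measured beside these lists. Fibroblast and pericyte markers rose in 5 of 10 members in sensitive cells with rapamycin (adjusted p = 0.0281, and 0.175 with an estimated correlation), including Pdgfrb (0.96 ± 0.10); without the third DMSO array, or without the first or the second sensitive rapamycin array, 3 rose, and with the mean of a gene's probe sets the adjusted p was 0.0748. Adjusted over the list alone 5 rose. In the resistant line against DMSO cells 5 of them fell and 2 rose (adjusted p = 0.199). Blood cell and microglia markers fell in 3 of 8 (adjusted p = 0.169), including Cd14 (-1.95 ± 0.11). Another of the 3, Cd52, lost its call without the first (adjusted p = 0.0931), the second (0.0552) or the third (0.0623) resistant array. Epithelial markers fell in 2 of 5 (adjusted p = 0.14), including Krt14 (-3.52 ± 0.25), and neural and glial markers fell in 4 of 9 and rose in 1 (adjusted p = 0.301). Adjusted over the list alone, 5 fibroblast and pericyte markers, 3 blood cell markers, 2 epithelial markers and 4 neural markers fell. The 2 endothelial markers tested were too few for camera; their median changes were 0.25 for rapamycin in sensitive cells, -0.02 for the resistant against the DMSO cells and -0.28 between the rapamycin groups.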

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

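No test in this part was chosen only after its result was seen. Probe sets without a single gene name take no part in the comparisons of genes, and many of them changed. In a limma fit of all probe sets above the filter, 3849 were of this kind. Called were 642 of them (16.7%) for rapamycin in sensitive cells, 1086 (28.2%) for the resistant against the sensitive DMSO cells and 1040 (27.0%) between the rapamycin groups. The shares among named probe sets were 29.9%, 46.3% and 51.1%. No explanation was tested for this difference.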

How the results depend on the processing

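The alternatives were all planned. For rapamycin in sensitive cells, the resistant against the DMSO cells and the resistant against the sensitive rapamycin cells, the counts of changed genes were 4523, 6581 and 7186. Leaving out each array in turn gave 3917 to 4714, 5864 to 6636 and 6633 to 7703, the highest count each time without the third DMSO array; an arm of 2 arrays shares its spread estimate with the other groups. A fit of all probe sets called 7574, 11819 and 12885, counting probe sets (27022 tested) and not genes. Every other planned fit stayed within 1.5 times the count. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated between -0.085 and 0.015, and with the number as a replicate block 4382, 6448 and 7100 genes were called. Shifted lists numbered 15, 14 and 20, but 5, 3 and 4 with an estimated correlation and 24, 31 and 33 with fry, which asks whether a list moves by itself. Without a filter on dim genes 22 lists were shifted in the resistant against the DMSO cells, with 18193 genes tested. Leaving out arrays gave 15 to 16, 14 to 16 and 20 to 21 lists. With 1 array left out, genes changed the same way against DMSO numbered 1068 to 1377, those turned between the rapamycin groups 2829 to 3377, and those changed against both sensitive groups 4668 to 5337; with the mean of a gene's probe sets they numbered 1044, 2789 and 4728.

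For 473 results of named genes, 9719 of 9869 values under alternatives kept direction and side of the threshold, 135 lost the call, 9 gained it and 6 reversed. With the mean of a gene's probe sets, Acly for rapamycin in sensitive cells reversed to -0.12 (-0.1164), Hif1a in the resistant against the DMSO cells to -0.26 (-0.2609), and Fkbp1a to -0.04389 against the DMSO cells and -0.04397 against the sensitive rapamycin cells. Without probe sets with an _x_ or _s_ suffix Fkbp1a reversed to -0.04916 and -0.2628. These settings use other probe sets of the same genes. Of 2466 values of lists 2340 were the same, 40 lost the call, 86 gained it and 0 reversed. The 3 groups of 6 arrays allow 10 splits each, too few for a share under 0.05: the real split, 1 of 10, called 4077, 6406 and 7688 genes with those 6 arrays alone, and the highest other split called 0. Without detection calls, a dim signal could not be told from background; without the filter at 22.2, 4274, 6427 and 7013 of 18193 genes were called.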

Other observations

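Chosen after results were seen were the tests of X stretches and of chromosome 18, the bootstrap intervals, the comparison of the genes around Myc with the change of Myc, the blood markers' share of the possible fall and their signal against the interferon list, and the naming of Pvt1. The bootstrap intervals are 95% intervals from resampling genes as if they were independent, with the arrays held fixed. They leave out the spread between arrays and any dependence between neighbouring genes. Lists of other pathways were not shifted in any comparison, yet held large changes in the resistant against the DMSO cells. Of 26 genes of apoptosis 13 fell and 6 rose, also when adjusted over the list alone (camera adjusted p = 0.0682), among them the inflammatory caspase Casp4 (-4.59 ± 0.22), Casp12 (-2.18 ± 0.09), Casp8 (-1.56 ± 0.08) and Birc3 (-2.48 ± 0.34). Of 21 p53 targets 11 fell and 6 rose (adjusted p = 0.14), with Ccng1 at -2.23 ± 0.10 and Gadd45a at -1.42 ± 0.11. Hypoxia-inducible factor targets fell in 10 of 24 and rose in 6 (adjusted p = 0.689), with Lox, which crosslinks collagen, at -2.85 ± 0.09 and Pdk1, which inhibits pyruvate dehydrogenase, at 1.36 ± 0.10. Wnt signalling genes fell in 4 of 28 and rose in 3 (adjusted p = 0.557), and the receptor Fzd1 changed by -2.68 ± 0.20.

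In the same comparison mTOR and PI3K pathway components rose in 17 of 37 and fell in 5 (adjusted p = 0.0766), with the kinase Sgk1 at -1.90 ± 0.09. Drug efflux and xenobiotic genes fell in 9 of 25 and rose in 5 (adjusted p = 0.491); Gstm2 fell (-1.52 ± 0.08) and Gsta4 rose (1.56 ± 0.10). NRF2 targets rose in 8 of 20 and fell in 6 (adjusted p = 0.746), and pentose phosphate genes rose in 5 of 8 and fell in 2 (adjusted p = 0.14), with transketolase, Tkt, at 1.67 ± 0.15. Adjusted over the list alone, 6 pentose phosphate genes rose and 11 hypoxia-inducible factor targets fell, and the other counts of these lists did not change. Rapamycin in sensitive cells lowered the cell cycle inhibitor Cdkn1a (-1.46 ± 0.16) and Birc5 (-2.65 ± 0.11) and raised Trp53inp1 (1.66 ± 0.31). The array's 3 control probe sets for the transferrin receptor moved with Tfrc: the 3-prime one had signals of 157 ± 10.4 in DMSO cells, 26.6 ± 5.29 in sensitive rapamycin cells and 321 ± 15.2 in resistant cells.

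Interferon response genes were lower in the resistant line, 34 of 36 by the test against DMSO cells. Under 2 other pseudocounts and 2 other scalings the lowest count was still 34, which argues against the pseudocount or the scaling between arrays. Blood cells or microglia in the sensitive cultures as the source of these transcripts could not be judged from their 8 markers. Of these, 1 was above the median level of tested genes in the sensitive cells, which by the rule set beforehand counted against this source. Their median signal in DMSO cells was 80.3, against 724 for the interferon list, but signals of different probe sets do not compare as amounts. They fell by a median share of 0.331 of the log2 fall to signal 0, against 0.684 (difference -0.353, bootstrap interval -0.708 to -0.059). Background in dim signals lowers that share as well. Shares ran from -0.049 to 0.705, and dim signals may be background. Cd14, at 607, fell by -1.95 and Lyz2 by -0.88, while Csf1r, at 155, changed by 0.002. Cd52 fell by -1.34, a call that was lost when any 1 resistant array was left out. Blood cells as a source of interferon were not tested. For the interferon receptors and their kinases, the rule set beforehand asked for a gene called lower by at least 1 on the log2 scale against both sensitive groups. It was met by 1 of 7 genes, Ifngr1. Lower mRNA of the interferon receptors or their kinases stays open: against the DMSO cells and the sensitive rapamycin cells Ifngr1 changed by -1.58 and -1.79, Jak1 by -0.38 and -0.83 and Jak2 by -0.62 and -1.25, all called, while Ifnar1 changed by -0.12 (adjusted p = 0.356) and -0.83 (adjusted p = 2.81e-06), Ifnar2 by 0.12 (adjusted p = 0.315) and -0.32 (adjusted p = 0.00792), Ifngr2 by -0.19 (adjusted p = 0.778) and -1.27 (adjusted p = 0.0332) and Tyk2 by -0.36 (adjusted p = 0.0562) and -0.36 (adjusted p = 0.0516).

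Myc was 3.81 higher in the resistant line, and the brightest Pvt1 probe set, its neighbour, 2.68 higher (adjusted p = 8.52e-11). Against gain of a chromosome region of several genes around Myc as the whole cause, the 10 nearest tested genes had a median change of 0.166 (bootstrap interval -0.633 to 0.774), the 5 before Myc 0.774, with 4 called higher, and the 5 after it -0.131, and none rose by more than 1.63. Against copy number differences over long chromosome stretches as the whole cause, the highest median of the 50 windows of 50 genes that hold Myc was 0.648 (bootstrap interval 0.288 to 0.789). A smaller gain as part of the rise stays open: the interval of the 10 genes spanned 0.557, the upper end of the central 95% of such windows, though their median was below it. The window of 50 genes around Myc, the one named beforehand, had a median of 0.0925, inside the shuffled range of -0.631 to 0.458. By the rule set beforehand this counted against long stretches. Of the 50 windows that hold Myc, which overlap and are not independent, 14 were above that range. The rule also asked for more windows beyond the range than shuffled orders allow. Over all chromosomes 422 of 11708 windows of 50 genes were beyond it, so that part was met. A run of 52 windows above the range on chromosome 15, that of Myc, spanned 101 genes from Ctnnd2 to Zfat. The highest median in that run was 0.657. Regulation of Myc itself, or gain of Myc and Pvt1 alone, was not tested.

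Xist, the RNA that silences an X copy, went from 1067 ± 171 in DMSO cells to 31.1 ± 6.34 in the resistant line (-4.52 ± 0.14). Of 395 other X-linked genes 233 fell and 18 rose. Their median lay -0.561 from that of autosomal genes (bootstrap interval over genes -0.625 to -0.465). This fall argues against expression from 2 active copies, though the interval leaves out the spread between arrays. Loss of the silenced copy stays open: escape genes lay 0.247 above other X-linked genes (8 genes, -0.136 to 0.689), set beforehand as counting against it, but that bound took the other X-linked genes as unmoved, while they fell, and 5 of the 8 escape genes were called lower and 1 higher (median -0.37). Loss of an X copy that was expressed, along with the silenced one, stays open too: in all 8 stretches of the X genes were lower than autosomal genes of like level (highest median -0.451). Chromosome 18 was low by a like amount (median -0.507 for 324 genes, 181 lower and 17 higher), against -0.178 to 0.166 for the other 18 autosomes. Lower copy number of whole chromosomes may therefore be a candidate explanation that DNA would have to test. Medians of whole chromosomes do not show shifts of parts. Windows of neighbouring genes above the shuffled range lay on chromosomes 2, 4, 5, 14 and 15. Their highest medians were 0.497, 0.605, 0.55, 0.548 and 0.689. All windows below that range lay on chromosome 18 and the X. The cause of the regional rises was not tested.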
